A study of Homo sapiens with 6 samples.

How the data were processed

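The samples were total RNA of HaCaT keratinocytes extracted with Trizol, from which biotinylated cRNA was prepared with the Affymetrix protocol, per the labels' protocols. The deposited values are log2 expression per probe set, normalised between arrays by the authors with RMA (robust multi-array average), per the submitters' processing notes. The software, its version and the probe set definition are not given in the sources used here. RMA corrects the background, brings the arrays to a shared distribution and summarises probes on the log2 scale. The values fit this, since each of the 6 arrays had a median of 3.90, quartiles of 3.23 and 6.69 and a range from 2.64 to 13.2. A shift shared by most genes would therefore be removed, and differences are relative to the bulk of the genes. No probe-level signal was used here, so a level above background could not be set for each probe set.

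Groups and plates were taken from the labels, with 3 irradiated and 3 unirradiated samples and 1 of each per plate. Of 24733 probe sets, 23934 (96.8%) carried 1 gene symbol in the annotation used. The remaining 799 carried none or several, which were not counted apart. Only probe sets with 1 symbol entered the gene-level test, and 0 of the other 799 passed the threshold when every probe set was tested on its own. Entrez identifiers of 23893 genes were found in the reference list of genes, and 0 symbols needed updating. For the 3 symbols with more than 1 probe set, the probe set with the highest mean was kept, which left 23931 genes. No filter on dim probe sets was used. Listed genes without a named probe set were not analysed here. No genomic coordinates are given, because the build is not given in the sources used here.

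Blue light was compared with control in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with the plate as a fixed block, as a two-sided moderated test. P-values were adjusted over all genes with the Benjamini-Hochberg method, and an adjusted p below 0.05 was the threshold. The block follows the stated design, in which each plate held irradiated and unirradiated cells. Deviations from the group means, across genes, correlated at 0.051, 0.055 and 0.058 between the irradiated and the control array of a plate. Between irradiated and control arrays of different plates they correlated at -0.058 to -0.0020. Deviations from a group mean sum to 0 within the group, so part of this contrast is built in. The labels give a plate number for each sample, and the pairing rests on those labels, since the correlations are all below 0.1. The data.table package, version 1.17.8, handled the values, and Python 3.11.15 with matplotlib 3.10.9 for figures.

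Before the data were examined, 28 gene lists were fixed for pathways, stress programmes and markers of keratinocytes and of other cell types. Each list was tested with limma's camera at a preset correlation between genes of 0.01, with the Benjamini-Hochberg adjustment over the lists. Fry and camera with an estimated correlation were run beside it. Members were adjusted over the list alone as well as over all genes. The rule for named genes was also fixed then. Up to 12 called genes per direction were to be named, filled up to 5 by smallest p where fewer than 5 were called. Of each list up to 4 called members were to be named, or the 2 members of smallest p where none was called. AHR, CYP1A1, CYP1B1, AHRR, TIPARP, NQO1, HMOX1, CDKN1A, FOS, OPN3, CRY1, PER1 and MKI67 were always named. The rule gave 74 genes, and genes named outside it are said to be so.

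The fit was tested on simulated data with the design of blue light against control on 3 plates, in 20 simulations of 23931 genes with 200 changed, 50 per fold. It recovered 0.2% of genes changed 1.25-fold, 31.6% at 1.5-fold, 93.1% at 2-fold and 99.3% at 4-fold, with 6.35 false calls per simulation. The 95% intervals covered the true value for 95.0% of genes. A list shifted by 0.19 was called in 20 of 20 simulations, and 2.22% of unshifted lists had a camera p below 0.05. The simulated genes varied independently, with the same spread on every array. Correlation between genes and an array that stands apart were therefore not tested. Each gene's simulated spread was limma's moderated one, already drawn towards a shared value, so spreads differed less between genes than in the data. The shares recovered may thus be too high for these data. They hold for 200 changed genes, since with fewer of them the adjustment is stricter. In the data HMOX1, at 2.15-fold, had a limma adjusted p of 0.92.

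Alternatives fixed before the data were examined were the fit without the plate term, the plate as a random block, filters on dim genes, other rules for probe sets, median centring, repeated quantile normalisation, a trended robust prior, array weights, a fold minimum of 1.5, an adjusted p of 0.1, a plain paired test, leaving out each plate, camera on ranks and camera with an estimated correlation. Leaving out each array in turn without the plate term, and array weights without it, were added after seeing the data. So was the comparison of list medians with 10000 random lists matched on mean log2 expression within 20 bins.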

Results

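Gene expression was measured in HaCaT cells, a spontaneously immortalised human keratinocyte line, 3 h after irradiation with blue light and in cells that received no light. The light came from LEDs with a peak wavelength of 453 nm placed at a distance of 55 mm. Irradiation lasted 7.5 min at 23 mW/cm², a fluence of 10.35 J/cm². The set held 6 Affymetrix arrays, with 3 arrays per group, and each of 3 plates of 96 wells gave 1 irradiated and 1 unirradiated sample. The title of the study concerns photobiomodulation, the modulation of cell behaviour by light, and a biphasic effect of blue light on proliferation. The comparison asks which transcripts differed between irradiated and unirradiated cells of the same plate. Log2 expression had a median of 3.90 on each array, and 23931 genes were tested. The plates served as replicates, and nothing in the labels says how far the cultures on them were grown separately. The p-values of single genes therefore measure the spread between these samples, which may be technical. Camera at its preset correlation compares the genes of a list with the other genes. Its p-values rest on the number of genes and the spread between them, not on the number of arrays. The number of arrays limits the precision.

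Genes controlled by NRF2, the transcription factor of the oxidative stress response, were higher as a set after blue light by camera, limma's test of a list against the other genes (Benjamini-Hochberg adjusted p 1.42e-07). The adjusted p = 0.861 with an estimated correlation, and fry, limma's test of whether the members move together, gave an adjusted p of 0.338. Of the 26 listed NRF2 targets 23 were measured, and 21 of these lay above 0 with a median log2 difference of 0.19, or 1.14-fold. Camera also called the list of nuclear-coded respiratory chain subunits, which as fixed also names ATP synthase genes, CYCS and the regulators PPARGC1A, TFAM and NRF1. Its median was 0.067 over 31 measured genes, or 1.05-fold (camera adjusted p 0.0285). This call had an adjusted p = 0.922 with an estimated correlation, and it ended without control replicate 3, where the median was 0.030, and without any 1 plate. No single gene passed the threshold: limma called 0 genes at a Benjamini-Hochberg adjusted p below 0.05, and the smallest adjusted p was 0.92. At an unadjusted p below 0.05 there were 905 genes, 502 higher and 403 lower, where chance alone gives 1196.55. A plain paired test and the limma fit without the plate term, each with the same adjustment, also called 0 genes, with 1036 and 821 at an unadjusted p below 0.05.

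Among the NRF2 targets, HMOX1 had the largest difference. HMOX1 encodes heme oxygenase 1, which degrades heme, and its log2 expression was 5.76 ± 0.46 (SD, n = 3) after blue light and 4.66 ± 0.16 (SD, n = 3) in controls. The difference of 1.10 (SE 0.22) corresponds to 2.15-fold with a 95% interval from 1.46 to 3.17, and the plates gave 1.10, 0.55 and 1.67. OSGIN1, an oxidative stress-induced growth inhibitor, differed by 0.58 (SE 0.12), with 0.37, 0.49 and 0.89 on the plates. NQO1, a quinone reductase, differed by 0.26 (SE 0.087). GCLC, GCLM, SRXN1 and ABCC2 were singled out after their values were seen, because they were the remaining members with an unadjusted p below 0.05. GCLC and GCLM, the subunits of the enzyme that limits glutathione synthesis, differed by 0.32 (SE 0.076) and 0.26 (SE 0.068). SRXN1, a sulfiredoxin, differed by 0.31, while ABCC2, an efflux pump, differed by -0.49 with -0.13, -0.35 and -1.01 on the plates. Without plate 3 the differences were 0.18 for SRXN1 and -0.24 for ABCC2. In all, 13 of the 23 members were higher on all plates and 1 was lower on all plates. None of them passed limma's test over all genes and 0 passed adjusted over the list alone, where the smallest adjusted p was 0.0563, with 7 at an unadjusted p below 0.05. Of 10000 random lists matched on mean log2 expression 0 had a median as high. The plate medians were 0.13, 0.13 and 0.25, and in control replicate 3, which stood apart from the other arrays, the list lay at -0.13 against the mean of controls 1 and 2.

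**Figure D1:**
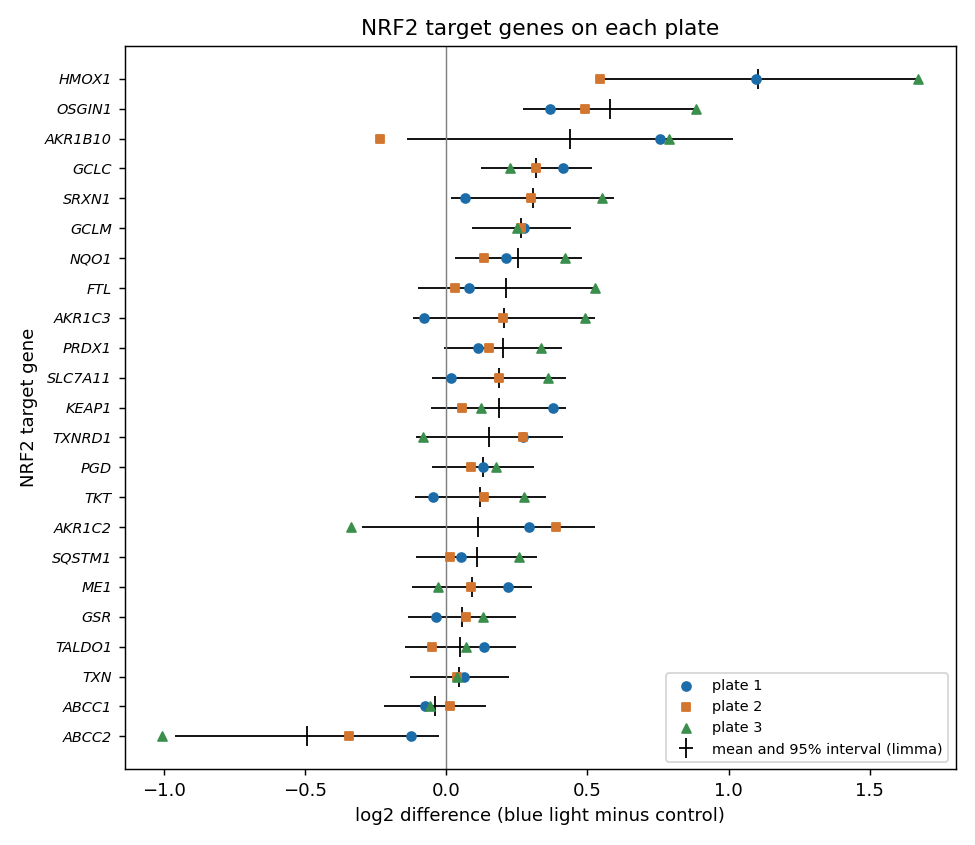
Log2 difference between blue light and control (horizontal axis) for the 23 measured NRF2 target genes (vertical axis). Coloured points are the 3 plates, and black ticks and bars are the mean and 95% interval from limma. Means lie above 0 for 21 genes, HMOX1 has the highest mean at 1.10 and ABCC2 the lowest at -0.49.

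The respiratory chain list had 23 of 31 measured members above 0, and 12 were higher on all plates. NDUFA2, a subunit of complex I, differed by 0.28 (SE 0.081) and COX5B, a subunit of complex IV, by 0.30 (SE 0.090). COX5B differed by 0.36, 0.43 and 0.12 on the plates. Camera gave the list a Benjamini-Hochberg adjusted p of 0.0285, and the adjusted p = 0.922 with an estimated correlation. By limma 0 members passed over all genes and 0 passed adjusted over the list alone, with 3 at an unadjusted p below 0.05. The plate medians were 0.024, 0.051 and 0.13. Without control replicate 3, in a fit without the plate term, the median was 0.030 and the adjusted p 0.202, and camera's call also ended without blue light replicate 2 (0.209), control replicate 1 (0.0709) or control replicate 2 (0.0515). With the plate term it ended without plate 1 (0.104), plate 2 (0.383) or plate 3 (0.193).

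**Figure D2:**
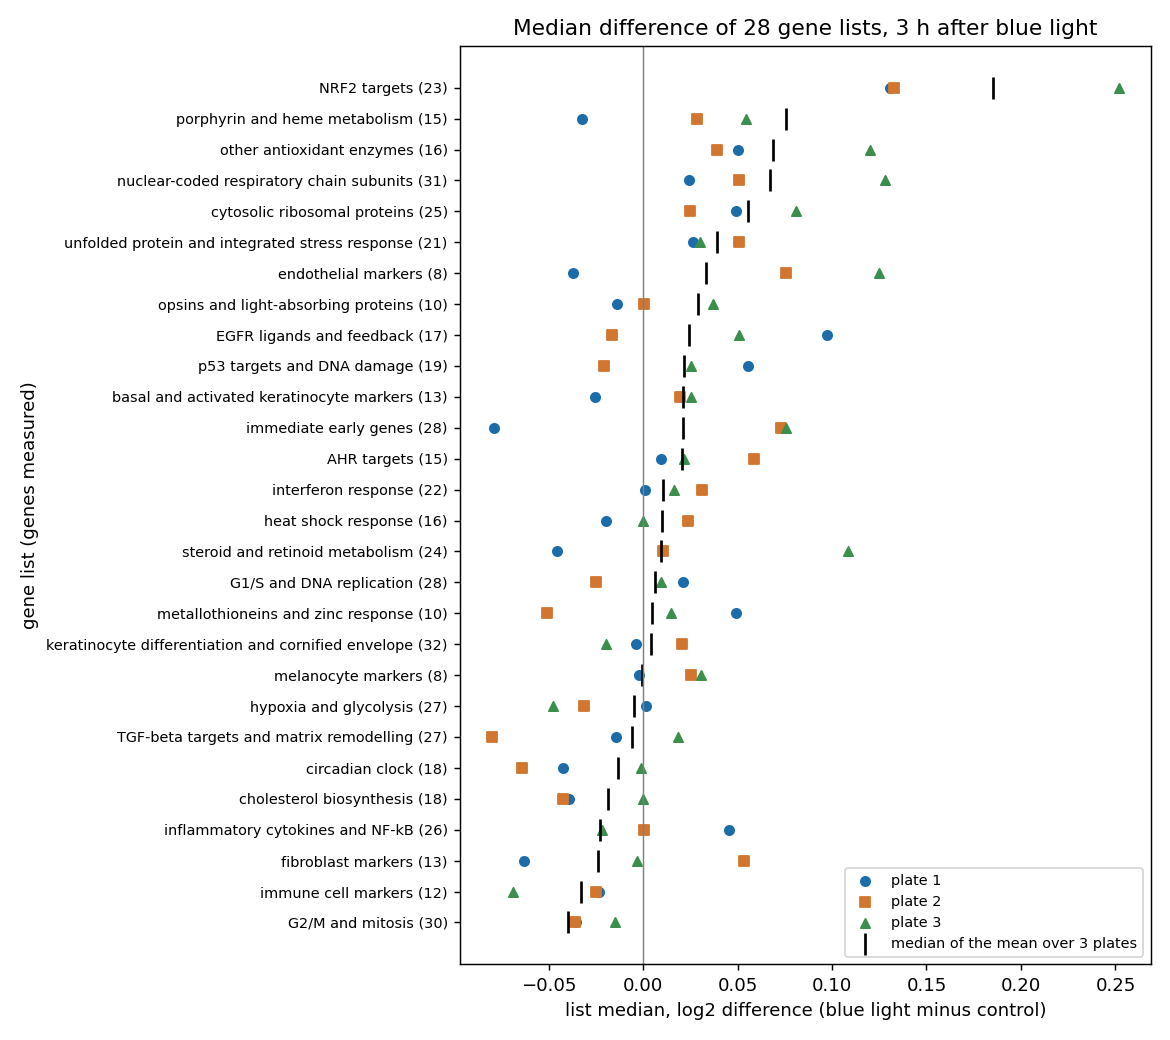
Median log2 difference between blue light and control (horizontal axis) of 28 gene lists (vertical axis, with the number of genes measured). Coloured points are the medians on each of 3 plates and black ticks the median of the mean differences. The NRF2 targets lie highest at 0.19, and the medians of the 26 lists not called run from -0.040 to 0.075.

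The other 26 lists were not called by camera, with Benjamini-Hochberg adjusted p from 0.304 to 0.987 and medians from -0.040 to 0.075. Over all 28 lists limma called 0 members adjusted over the list alone, and fry, on 2 residual degrees of freedom, called 0 lists. Targets of the aryl hydrocarbon receptor AHR, a sensor of xenobiotics and of tryptophan photoproducts, had a median of 0.021 over 15 genes (adjusted p 0.859). CYP1A1, a canonical AHR target, differed by 0.13, with a 95% interval from -0.066 to 0.33. AHR itself differed by -0.066 (interval -0.25 to 0.12), CYP1B1 by 0.014 and AHRR, the AHR repressor, by 0.064. CYP1B1 was at -0.0040 without plate 2 and 0.030 without plate 3, and AHRR at -0.075 without plate 1 and 0.19 without plate 3. TIPARP, an AHR-induced ADP-ribosyltransferase, differed by 0.28 (SE 0.074), with 0.21, 0.24 and 0.37 on the plates. LRAT, a lecithin retinol acyltransferase, differed by -0.46 (SE 0.096). None of these genes passed the threshold.

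Lists of other stress programmes were not called by camera, and several of the named members moved when 1 plate was left out. Antioxidant enzymes outside the NRF2 list had a median of 0.069 over 16 genes (adjusted p 0.304), with 12 above 0, and camera called it without blue light replicate 1 and the plate term (0.0424). Of these, TXN2, mitochondrial thioredoxin, differed by 0.38 and SOD1, cytosolic superoxide dismutase, by 0.21, and without plate 3 by 0.20 and 0.14. The unfolded protein and integrated stress response had a median of 0.039 (adjusted p 0.586), with PPP1R15A at 0.34, or 0.17 without plate 3, and DNAJB9 at -0.22, or -0.15 without plate 2. Heat shock genes had a median of 0.010 (adjusted p 0.869). HSPB8, a small heat shock protein, differed by 0.71 (SE 0.19), with 0.58, 0.30 and 1.26 on the plates and 0.44 without plate 3, and control replicate 3 lay at -1.56 against the other arrays for this gene. HSP90AA1 differed by -0.21, and by -0.055 without plate 3. The metallothionein and zinc list had a median of 0.0048 (adjusted p 0.869), with MT1X at 0.28, or 0.17 without plate 3, and MTF1, the zinc-sensing transcription factor, at -0.10, or -0.066 without plate 1. p53 targets had a median of 0.022 (adjusted p 0.859), with TP53I3 at 0.30 and SESN1 at 0.26, the latter at 0.15 without plate 1 and 0.39 without plate 2. CDKN1A, the cell cycle inhibitor p21, differed by 0.14 (interval -0.21 to 0.49), with 0.23 without plate 1, 0.23 without plate 2 and -0.048 without plate 3. Hypoxia and glycolysis genes had a median of -0.0049 (adjusted p 0.859), with ANKRD37 at -0.35, or -0.17 without plate 3, and BNIP3L at -0.18. Genes of porphyrin and heme metabolism had a median of 0.075 over 15 genes (adjusted p 0.859), with plate medians of -0.033, 0.028 and 0.055. HMOX1, which the NRF2 list also holds, was its member of smallest p at 1.10 and its only one with an unadjusted p below 0.05, while TFRC, the transferrin receptor, differed by -0.16, with -0.16, -0.16 and -0.17 on the plates.

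Genes of signalling and inflammation gave medians near 0. Immediate early genes had a median of 0.021 (adjusted p 0.869), with IER5 at 0.27, NR4A2 at 0.17 and FOS, a subunit of AP-1, at -0.11. IER5 was at 0.16 without plate 1, and NR4A2 at 0.29 without plate 2 and 0.099 without plate 3. FOS was at 0.050 without plate 1 and -0.24 without plate 2. EGFR ligands and feedback genes had a median of 0.025 (adjusted p 0.869), with LRIG3 at 0.17 and EREG at 0.14. Inflammatory cytokine and NF-kB genes had a median of -0.023 (adjusted p 0.869). Among them PTGS2, which makes prostaglandins, differed by -0.26 and CSF3, a granulocyte growth factor, by 0.27. Interferon response genes had a median of 0.011 and a mean of -0.00015 (adjusted p 0.869), so that the signs differed, with IFIH1 at 0.22 and IRF9 at 0.16. TGF-beta targets and matrix remodelling genes had a median of -0.0060 (adjusted p 0.859), with MMP3 at -0.29, or -0.17 without plate 3, and SKIL at -0.15.

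Proliferation genes were not called by camera at 3 h. G1/S and DNA replication genes had a median of 0.0064 over 28 genes (adjusted p 0.869), with E2F2 at 0.26, or 0.15 without plate 3, and CDT1 at 0.18. G2/M and mitosis genes had a median of -0.040 over 30 genes (adjusted p 0.859), and 11 lay above 0. HMMR differed by -0.22 (SE 0.076), CENPE, a mitotic kinesin, by -0.19 and MKI67, the proliferation marker Ki-67, by -0.10 (interval -0.28 to 0.07). Without plate 3 the value of CENPE was -0.12. Cytosolic ribosomal protein genes had a median of 0.056 (adjusted p 0.486), with RPL7 at 0.29 and RPS24 at -0.21. RPL7 had a mean log2 expression of 3.31, below the array median of 3.90. Cholesterol biosynthesis genes had a median of -0.019 and a mean of 0.012, with camera pointing down (adjusted p 0.869). SREBF2, the regulator of that pathway, differed by -0.15 and EBP by 0.18, the latter by 0.28 without plate 1 and 0.037 without plate 3.

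Keratinocyte differentiation and cornified envelope genes had a median of 0.0042 over 32 genes, while their mean was -0.017 and camera pointed down (adjusted p 0.869). The median log2 level of this list was 3.73, against 4.02 for steroid and retinoid genes and 3.89 for opsins. The array median was 3.90, so many members of these lists were dim, and a median difference near 0 says little of them. SPRR1A, a cornified envelope precursor, differed by -0.37 (SE 0.081), with -0.36, -0.25 and -0.49 on the plates, and FLG, filaggrin, by -0.19 (SE 0.069). Basal and activated keratinocyte markers had a median of 0.021 (adjusted p 0.869), with CDH3 at -0.13 and SFN at 0.11, or 0.063 without plate 3. Steroid and retinoid metabolism genes had a median of 0.0093 and a mean of -0.0075 with camera pointing up (adjusted p 0.935), and RARG, a retinoic acid receptor, differed by 0.28, or 0.16 without plate 3. Circadian clock genes had a median of -0.013 over 18 genes (adjusted p 0.859). The period genes PER1 and PER2 differed by -0.35 (SE 0.11) and -0.36 (SE 0.12), and PER1 gave -0.29, -0.16 and -0.60 on the plates. CRY1, a cryptochrome of the clock, differed by -0.0078, with -0.0029, 0.026 and -0.047 when plates 1, 2 and 3 were left out in turn. Opsins and light-absorbing proteins had a median of 0.029 and a mean of -0.030 with camera pointing up (adjusted p 0.987). OPN3, the opsin encephalopsin, differed by 0.044 (interval -0.14 to 0.23), TRPV1 by -0.21 and RGR by -0.46. Without plate 3 these were 0.027, -0.11 and -0.085, and PER1 was at -0.23. OPN3 was at 0.027 without plate 1 and 0.078 without plate 2, and TRPV1 at -0.33 without plate 2.

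Markers of other cell types gave small medians. Their lists had median log2 levels of 3.17 to 3.43, below the array median of 3.90, so small differences say little of them. Fibroblast markers had a median of -0.024 (adjusted p 0.859), with COL1A1 at -0.22 and COL1A2 at -0.16, and immune cell markers had a median of -0.033 (adjusted p 0.859), with CD207 at -0.17 and CD14 at 0.11. COL1A1 was at -0.36 without plate 1 and -0.14 without plate 2. Without plate 3 COL1A2 was at -0.080 and CD207 at -0.055. Endothelial markers had a median of 0.033 (adjusted p 0.859), with ESAM at 0.19 and CDH5 at 0.10. Melanocyte markers had a median of -0.00035 and a mean of 0.0072 with camera pointing up (adjusted p 0.869), with TYRP1 at 0.093 and SOX10 at 0.073. SOX10 was at 0.14 without plate 1 and -0.016 without plate 2.

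Among single genes ranked by p, NMRAL2P, a pseudogene of the NmrA-like family, came first with a log2 difference of 0.69 (SE 0.069), or 1.62-fold with a 95% interval from 1.43 to 1.83. Its plates gave 0.66, 0.69 and 0.73. The next genes with positive differences were CRHR1 at 0.62, TXNRD3NB at 0.57, B4GALNT3 at 0.49 and FAM21EP at 0.42. With negative differences, EIF1AX, a translation initiation factor, came first at -0.68 (SE 0.082), or 0.626-fold, with -0.61, -0.60 and -0.82 on the plates. It was followed by POM121L10P at -0.57, DNAL4 at -0.60, TAS2R14 at -0.59 and MCEE at -0.45. These 10 genes were the same in sign on all plates and were not past the threshold, with a limma adjusted p of 0.92 for each. Only 3 genes differed by 2-fold or more, HMOX1, H2AB1 and IGHV1-3, the latter pair named after their values were seen. H2AB1 gave 0.25, -0.0049 and 3.00 on the plates and IGHV1-3 gave -0.076, -0.53 and -2.58. Without plate 3 their differences were 0.12 and -0.31, and without plate 2 that of H2AB1 was 1.62.

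**Figure D3:**
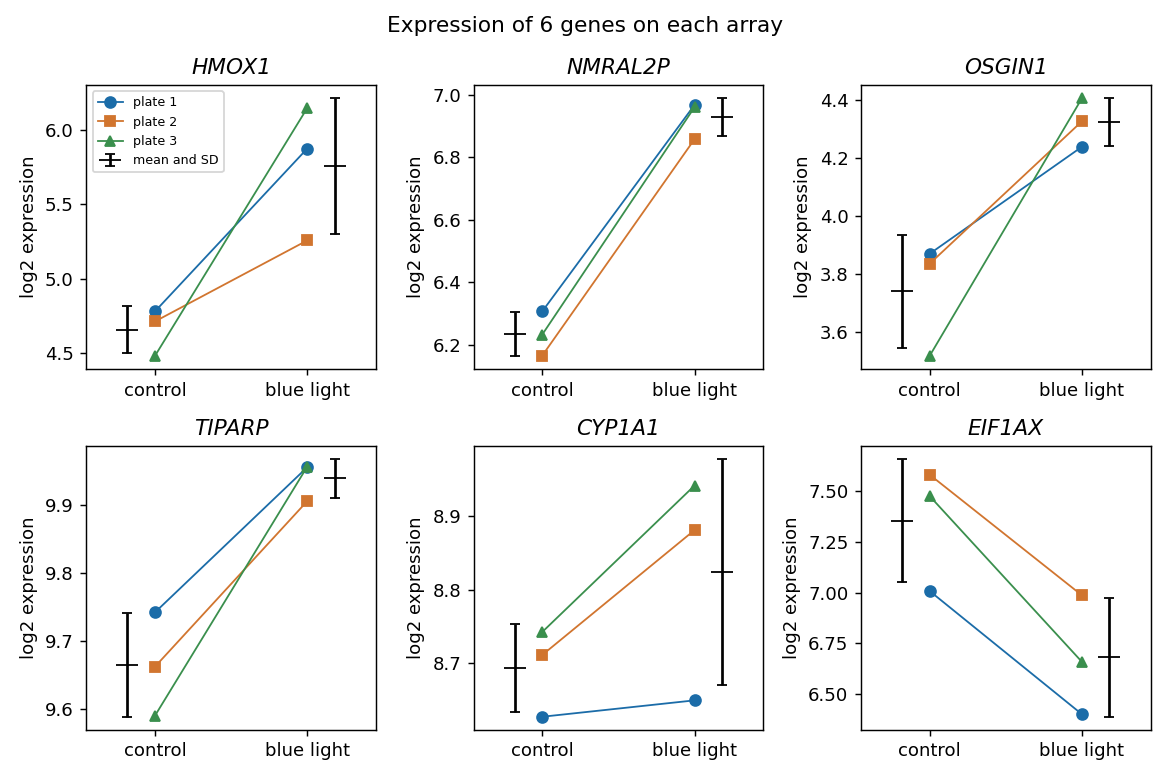
Log2 expression (vertical axes) of 6 genes on each array, control on the left and blue light on the right of each panel, with lines joining the arrays of a plate. Black marks are the mean and SD of 3 arrays. HMOX1 differs by 1.10, NMRAL2P by 0.69, OSGIN1 by 0.58, TIPARP by 0.28, CYP1A1 by 0.13 and EIF1AX by -0.68, and none passed the threshold.

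The intervals bound the measured difference of each gene taken singly, not of all genes jointly. Dim genes were not filtered out, and the lower quartile of each array, 3.23, lay near its lowest value, 2.64. For such genes a narrow interval need not bound a change in expression. The median SE was 0.087, the 95% interval typically reached 0.22 to either side on the log2 scale (median over genes), or 1.17-fold, and 98.9% of genes had an interval within 2-fold and 91.2% within 1.5-fold. Genes of the same sign on all 3 plates numbered 2986 higher and 3189 lower, together 25.8% where chance gives 25%. Of 80 named genes, 28 moved by over 1.5 times or turned in sign without plate 3, 25 of them to a smaller value or the other sign, against 11 without plate 1 and 12 without plate 2. Control replicate 3 correlated with the other arrays at 0.988 to 0.989, while the remaining 5 arrays correlated with each other at 0.996 to 0.998.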

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

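Leaving out single arrays and array weights without the plate term were chosen after seeing the data. All 23 alternatives for the gene counts called 0 genes by their adjusted p, and the smallest adjusted p among them was 0.141, from the plain paired test. They had 483 to 1273 genes at an unadjusted p below 0.05. The 483 came from the filter that kept genes above the median level. That filter tests fewer genes, so these counts do not share 1 chance level. Some alternatives could hardly differ from the main fit. The fold minimum can only remove calls, and averaging probe sets alters 3 genes. Repeated quantile normalisation acts on arrays that already share a distribution. The adjusted p of 0.1 reuses the main tests and could not lose a list called there. Camera called the NRF2 targets in 23 of 24 alternatives, with adjusted p from 2.02e-11 to 1.27e-04, and lost them with an estimated correlation (0.861). The respiratory chain list kept its call in 14 of 24, and its adjusted p was 0.121 with the milder filter on dim genes, 0.115 with array weights and no plate term, 0.922 with an estimated correlation, and 0.0201 to 0.383 when a plate or array was left out. The number of lists called, 2, became 1 with that filter, 1 with array weights and no plate term, 0 with an estimated correlation, and 1 to 3 when a plate or array was left out, the list gained being the other antioxidant enzymes (0.0424, without blue light replicate 1; 0.0513 to 0.922 otherwise). With an estimated correlation camera uses the residual degrees of freedom of the fit, here 2, in place of the number of genes, which raises its p by construction. The cause of the other losses was not tested. Without the replicate block, 821 genes had an unadjusted p below 0.05, 0 genes and 2 lists were called, and the adjusted p was 2.38e-09 for the NRF2 targets and 0.0269 for the respiratory chain list, so no call changed. Of 80 named genes 6 changed sign in some alternative: AHRR was -0.042 with array weights and no plate term, and over the plates and arrays left out AHRR ran from -0.17 to 0.25, FOS from -0.24 to 0.050, SOX10 from -0.016 to 0.19, CYP1B1 from -0.0040 to 0.036, CRY1 from -0.047 to 0.042 and CDKN1A from -0.048 to 0.23; the cause was not tested. A fold minimum gives no value for lists. Signal over background was not analysed here and limits what can be said of dim genes.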

Other observations

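The screen of gene families, and the tests of control replicate 3 on the lists, of a mislabelled sample, of matched random lists and of other splits of the arrays, were chosen after the results were seen. Of 17 families chosen by symbol, camera called 4, and the others were not called. The 76 genes of mitochondrial ribosomal proteins had a median log2 difference of 0.051 with 58 above 0, and a Benjamini-Hochberg adjusted p of 0.00205, or 0.00520 without control replicate 3 and the plate term. The adjusted p = 0.392 with an estimated correlation. Its plate medians were 0.064, 0.056 and 0.064. The 39 proteasome subunits had a median of 0.047, with 29 above 0, and an adjusted p of 0.0182, or 0.00520 without that array. The adjusted p = 0.392 with an estimated correlation, and the plate medians were 0.045, 0.033 and 0.057. Histones had a median of 0.080 and complex I subunits a median of 0.069, with plate medians of 0.071, 0.013 and 0.064 for histones and 0.043, 0.037 and 0.15 for complex I. The respiratory chain list also holds complex I subunits, so the call of that family repeats the call of the list in part. Histones and complex I were close in their tests. Each of these 2 families had a camera adjusted p of 0.0337, or 0.105 for histones and 0.104 for complex I without control replicate 3. With an estimated correlation the adjusted p = 0.392 for these as well, and for all 4 families that test rests on 2 residual degrees of freedom.

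The NRF2 targets were called by camera with a median of 0.19, and the adjusted p was 0.861 with an estimated correlation, on 2 residual degrees of freedom. The estimated correlation was 0.016, close to the preset 0.01, so the higher p comes largely with the change in degrees of freedom. An estimate from 6 arrays is itself imprecise. The tables argue against control replicate 3 as the whole cause, since the median was 0.14 without it (adjusted p 2.68e-10), against HMOX1 and OSGIN1, the 2 strongest members, since the adjusted p was 1.41e-05 without them, and against signal level, as 0 of 10000 lists matched on it had a median as high. The 10 splits of the arrays are too few for a share under 0.05: 1 of 10 gave a camera p as small, with 5.07e-09 for the real split and 2.66e-04 as the smallest of the others. That smallest value belongs to a split that parts plate 1 alone and so repeats the real contrast on that plate, while the 3 other splits that part all plates gave 0.296, 0.00836 and 0.0577. Each of those 3 keeps the real contrast on all plates but 1, up to an overall sign, so none is free of it. A response of NRF2 targets to blue light is a hypothesis that these values are consistent with, and correlation among the members stays open.

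The respiratory chain list had a median of 0.067. Camera's adjusted p was 0.922 with an estimated correlation, which was 0.047, on 2 residual degrees of freedom. Control replicate 3 may account for much of it, since the median without that array was 0.030, below 0.034, the value at which the list would have lost 50% of it, while the medians without each other array ran from 0.066 to 0.099. The splits are too few for a share under 0.05: 1 of 10 gave a camera p as small, with 0.00204 for the real split and 0.0407 as the smallest of the others, which parts plate 3 alone and so sets blue light replicate 3 against control replicate 3. The 3 other splits that part all plates gave 0.990, 0.256 and 0.0783, and each keeps the real contrast on all plates but 1, up to an overall sign. A response to blue light stays open as well.

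Control replicate 3 stood apart, with 290 genes over 2-fold from the mean of the other 5 arrays, 216 higher and 74 lower, against at most 9 for any other array measured the same way. Cells of another type did not show in 4 marker lists, whose highest median deviation was 0.036, for immune cells. These lists had median levels of 3.17 to 3.43, near the lowest value of 2.64, so a small share of such cells cannot be excluded. Immune markers went both ways, with TYROBP at 0.62, CD207 at 0.34, PTPRC at 0.24 and LYZ at 0.0093. CD68, the brightest, lay at -0.092, FCER1G at -0.29 and ITGAM at -0.30. CCL18 at 2.78, IGHV1-3 at 2.59 and KIR2DL3 at 2.43, genes of immune cells named after their values were seen, were its highest deviations. They stay unexplained, and DAAM2-AS1 at 2.34 and MIR4530 at 2.30 came next. Dim probe sets alone are argued against, since the spread of deviations among the brightest genes was 2.22 times that of the other arrays. An irradiated sample under a control label cannot be judged from the NRF2 targets. Their use assumes that blue light raises them, which is a hypothesis from these same arrays. In control replicate 3 they lay at -0.13 against the mean of controls 1 and 2, and in irradiated arrays at 0.097 to 0.20. The size of its shift thus lies within theirs. Controls 1 and 2, at -0.016 and 0.016, are set against their own mean. The bootstrap interval of -0.19 to -0.017 resamples members of the list and holds no spread between arrays. A difference in RNA or hybridisation stays open, and the design names no biological difference of this sample to test.

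The count of 0 genes by limma cannot be weighed by other splits, because 10 of 10 splits give at least 0. With the plate term, a split that parts 1 plate alone compares the arrays of that plate, and 6 of the 10 splits are of this kind, each fit occurring 2 times. The highest count, 833 genes with 6107 at an unadjusted p below 0.05, sets blue light replicate 3 against control replicate 3, 1 array against 1, so the structure of the samples it points to is control replicate 3 standing apart, and it adds no further evidence. Of the 10 splits 3 called 2 lists, the real one included, so the highest of the others was 2, in the split that parts plate 2 alone. Among the 4 splits that part all plates, the real one called 2 lists and the others 0, with 0 genes each and 905, 751, 914 and 1047 at an unadjusted p below 0.05. Those other splits keep the real contrast on all plates but 1, up to an overall sign, so they are not free of it.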
